A study of Homo sapiens and Mus musculus with 42 samples.

How the data were processed

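Polyadenylated RNA was sequenced from the human lung adenocarcinoma cell line A549 and from lungs of ICR mice. Per the labels' protocols, RNA was extracted with Trizol, and libraries were made with a TruSeq kit that marks strand and read in paired ends on an Illumina NovaSeq instrument. The labels give 42 samples in 4 experiments. The high experiment has 8 A549 samples, 2 each for medium, 10 mM ammonium nitrate, 5 mM ammonium sulfate and a 5 mM mixture of both. The moderate experiment has 12 A549 samples, 2 each for a control and mixtures at 10 nM, 100 nM, 1 uM, 10 uM and 100 uM. The composition experiment has 18 A549 samples, 3 each for a control and 5 nitrate and sulfate compositions that sum to 200 uM. The mouse experiment has 2 control lungs and 2 lungs of mice that breathed air with nitrate and sulfate particles. The group with 200 uM nitrate was taken from the sample titles, because its treatment label repeats that of the group with 200 uM sulfate, and the header lines of the composition file also list 200 uM nitrate. The labels do not say that samples of a group came from separate cultures.

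Per the submitters' processing notes, bcl2fastq, HISAT2 2.1.0, featureCounts and DESeq2 1.30.1 were used with the genome builds hg38 and mm10. The gene tables used here hold 1 fold change per gene and comparison, made by the authors, and 0 columns of values per sample. No standard error, p-value per gene, mean level or depth came with the fold changes, so the depth behind each value is unknown and no test per gene, replicate check or interval was possible. The deposited fold changes were taken as log2 values because the submitters' processing notes name DESeq2, and as treated over control. Neither the log base nor the direction is stated in the headers, and every direction given here rests on both assumptions. The composition columns, whose headers are 2 lines of doses, were read the same way as log2 fold changes by the authors. The authors' GO tables hold a deposited p-value per term, its -log10 value and the number and percent of a term's genes that the authors counted, per the file headers. Whether those p-values were adjusted is not stated. They list only 57 terms for the high, 51 for the moderate, 24 for the composition and 69 for the mouse experiment. How these terms were chosen is not stated, and all 69 mouse terms have p under 0.05. Which kind of term comes first therefore depends on that choice.

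What the tables list was tested on the files. The high table lists 1541 genes, each with an absolute fold change of at least 1.50 in 1 or more comparisons. The moderate table lists 423 genes, each reaching 1.00 in size. The composition table lists 660 genes, 83 of them under 1 in all 5 comparisons, with a lowest maximum of 0.76, so its selection rule is not known. The mouse table lists 15769 genes with no selection on size. The design fixed before the data were examined used an adjusted p of 0.05, which these tables do not give. A fold size was used instead, chosen after the tables were seen: 1.5 on the log2 scale (2.83-fold) in the high table and 1 (2-fold) in the others. For named genes, the rule was the 10 higher and 10 lower genes with the largest absolute fold change in each comparison, plus up to 10 members of gene lists fixed before the data were examined, without the criteria on adjusted p and mean level. List members were taken by the size of their fold change for the same reason.

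Human identifiers were matched to symbols, from a table of gene names and otherwise from GENCODE 29, for 1541 genes of the high table, 422 of the moderate table and 659 of the composition table. Positions are from GENCODE 29, which uses the same assembly as hg38. The mouse table pairs no symbols with its identifiers, and only the 87 genes that the authors' mouse GO table names could be named. An annotation of the mouse genome was not used here. For 26 human lists, the members past the fold size were counted by direction, and the share higher was compared with the table's own share by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the lists of a comparison that had at least 1 such member. The 31 mouse lists were counted over the 87 named genes with no test. Genes of a list are not independent samples, so these p-values describe the lists in these tables and not the spread between cultures.

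Genes listed by 2 experiments were compared by the share with the same sign, with a two-sided exact binomial test against 50% and adjustment over 21 pairs of comparisons. Comparisons within an experiment share their control libraries. Unchanged groups against shared controls were therefore simulated for 400000 genes, selecting the 1%, 5% or 20% of genes with the largest absolute difference. The controls could not be split, and the number of genes tested is unknown, so no overlap of independent lists and no covariance could be set beside the observed values. Because 50% ignores GC content and the excess of lower genes, the share with the same sign was also set against signs paired at random within 3 ranges of GC content, by an exact test chosen after the shares were seen. GC content and length were taken from each gene's longest transcript in GENCODE 29, protein-coding where there was one. Higher and lower genes were compared by the area under the curve with a 95% interval from 2000 bootstrap resamples of genes, and by a two-sided permutation test of the difference in medians with 100000 resamples.

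The list test was tested on simulated directions with 200 runs per comparison. With the fold sizes of the high mixture comparison and its 1541 genes, a list of 12 genes all set higher was recovered in 100% of runs and a list of 6 in 0%, and 0.225% of unchanged lists were called. Lists with few members past the fold size therefore had little or no power there. A second form of the test, added after the data were seen, took each member's chance of being higher from the 50 genes nearest in GC content. With direction set by GC content alone in that comparison's 1541 genes, the first form called 45.4% of unchanged lists alike in GC content, and the second 0.65%. Alternatives for fold size, GO p-value and overlap are given in the closing section. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.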

Results

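Gene expression was compared in A549 cells, a human lung adenocarcinoma line used as a model of alveolar epithelium, after ammonium nitrate, ammonium sulfate or both, and in mouse lung after inhaled particles of these salts. The series title names the toxicity of inorganic ions of particulate matter, their passage into lung and the disruption of cell metabolism as its subject. Each group had 2 samples, except in the composition experiment, where it had 3. The values are fold changes from the authors' deposited tables, taken as log2 and as treated over control, which the tables do not state. They come with no error, so whether a gene differed by more than the spread between samples could not be tested, and depth is unknown.

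At millimolar doses, immediate early genes and inflammatory genes had lower fold changes, and genes of cholesterol synthesis had higher ones. EGR1, a transcription factor induced within minutes of stimulation (ENSG00000120738, chromosome 5, 138465490 to 138469315), was at -7.05 with nitrate, -7.41 with sulfate and -6.93 with the mixture in the authors' deposited table. FOSB, a subunit of the AP-1 transcription factor, was at -6.37, -6.30 and -5.42 in the authors' deposited table. Of the 27 immediate early genes fixed as a list, 14 were listed, and 10, 11 and 13 of them passed a fold size of 1.5 with nitrate, sulfate and mixture, all lower. The exact binomial test against the share of higher genes in each comparison gave adjusted p = 0.0149, 0.00828 and 0.00179. All 3 treatments were compared with the same 2 control samples. Calls of a list in several treatments, here and below, are therefore not separate results, and a deviation of those controls would enter each of them. NR4A3, a nuclear receptor, was at -2.60, -2.81 and -4.94, and DUSP1, a phosphatase of MAP kinases, at -1.99, -1.91 and -2.14 in the authors' deposited table.

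Cytokine and NF-kB genes shared that direction. Of 29 inflammatory genes, 19 were listed, and 17 of the 18 past the fold size with nitrate, 15 of 16 with sulfate and 12 of 14 with the mixture were lower (exact binomial, adjusted p = 0.00401, 0.00779 and 0.0475). IL6 was at -4.23, -4.13 and -4.39, and CXCL8, a chemokine that attracts neutrophils, at -4.14, -3.80 and -2.85 in the authors' deposited table. TNFAIP3, an inhibitor of NF-kB, stood at -3.71, -3.36 and -2.88 in the authors' deposited table. LCN2, an iron-binding defence protein, went the other way at 1.95, 2.66 and 2.64, as did IL1B at 0.62, 0.94 and 2.60, in the authors' deposited table. IL23A was at -4.15, -3.31 and -4.93, and IL11 at -3.69, -3.38 and -4.90, in the authors' deposited table. CCN1, CCN2 and ANKRD1 ranged from -5.14 to -3.16 over the 3 treatments in the authors' deposited table.

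Sterol synthesis stood on the other side. Of 24 cholesterol genes, 18 were listed, and the 10, 12 and 17 past the fold size with nitrate, sulfate and mixture were all higher (exact binomial, adjusted p = 0.00401, 0.00177 and 0.000156). LSS, which closes the sterol ring, was at 2.26, 2.44 and 3.27 in the authors' deposited table. INSIG1, a sterol-regulated gene of the endoplasmic reticulum, was at 2.60, 2.40 and 2.88 in the authors' deposited table. FASN, the fatty acid synthase, was at 2.54, 2.55 and 3.21 in the authors' deposited table, and the 4 listed members of the fatty acid list were higher with the mixture but did not pass the exact binomial test (adjusted p = 0.123). ALDOC, a glycolytic aldolase (ENSG00000109107, chromosome 17, 28573115 to 28577264), had the highest mixture value in the authors' deposited table, 6.17, and was at 4.11 and 4.37 with nitrate and sulfate. DEPP1, which is induced by FOXO factors, was at 4.80, 5.10 and 4.13, and the heat shock gene HSPA1A at 4.60, 4.37 and 4.80 in the authors' deposited table. HSPA1A shares most of its sequence with HSPA1B, so its assignment is uncertain.

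**Figure D1:**
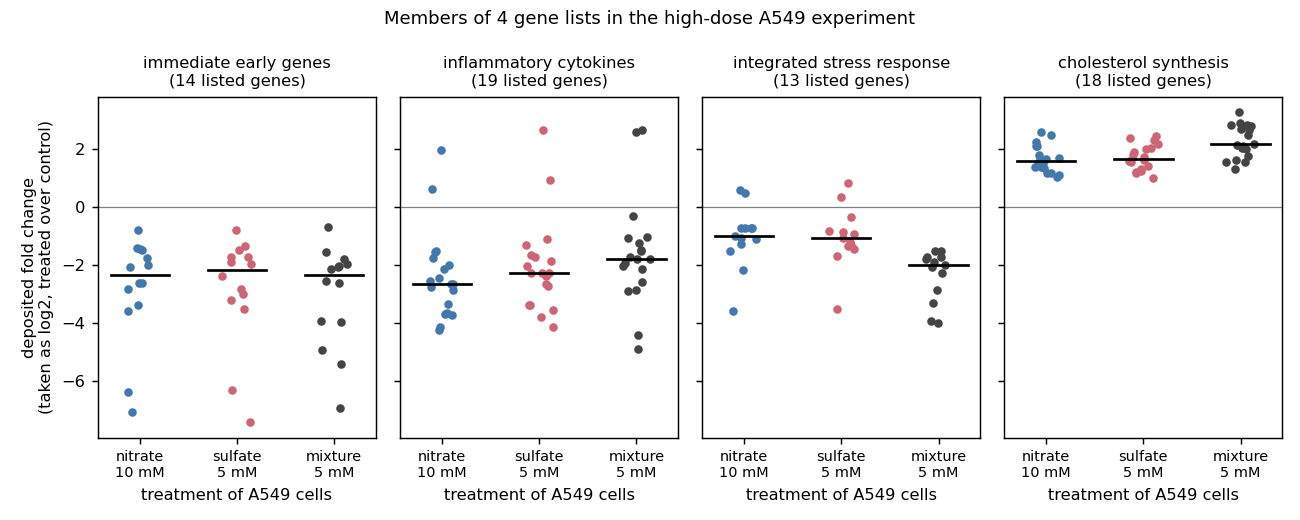
Deposited fold changes (vertical axis, taken as log2, treated over control) of the listed members of 4 gene lists in A549 cells with 10 mM nitrate, 5 mM sulfate or the 5 mM mixture. Each point is 1 gene, spread sideways for legibility, and black lines are medians. Immediate early genes lie below 0 and cholesterol genes above 0 in all 3 treatments.

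Some groups passed the test with the mixture alone, and the difference between treatments was not tested. All 13 listed genes of the integrated stress response, the programme run by ATF4, passed the fold size with the mixture. They were all lower (exact binomial, adjusted p = 0.00179), against 2 past it with nitrate and 2 with sulfate. Of the 1541 listed genes, 1338 passed with the mixture, 650 with nitrate and 791 with sulfate, so such counts favour the mixture. The median of the 13 genes was lower with the single salts too, at -1.002 with nitrate and -1.050 with sulfate, against -2.002 with the mixture. Single members were higher, up to 0.60 with nitrate and 0.82 with sulfate. DDIT3 was at -2.16, -1.69 and -3.98, and ALDH1L2, a mitochondrial folate enzyme, at -1.28, -1.31 and -2.86 in the authors' deposited table. CTH, which makes cysteine, was at 0.49 and 0.36 with the single salts and -1.89 with the mixture in the authors' deposited table. Glycolysis and hypoxia genes were higher in 12 of 13 cases with the mixture (exact binomial, adjusted p = 0.00965), including CA9, a carbonic anhydrase, at 3.85 in the authors' deposited table. ADM, a vasodilator peptide gene, was the lower one at -2.44 in the authors' deposited table. With each member compared with genes alike in GC content, that list no longer passed (adjusted p = 0.676). Of the interferon list, 6 of 6 were higher with the mixture (exact binomial, adjusted p = 0.0478), a call lost at a fold size of 1, where GBP1 and IRF1 entered as lower genes (adjusted p = 0.311). IFIT1, an antiviral gene, was at 2.95, 3.01 and 3.09 in the authors' deposited table. For the NRF2 list of antioxidant genes, which treatments passed depended on the form of the test. The 5, 5 and 7 members past the fold size with nitrate, sulfate and mixture were all higher (exact binomial, adjusted p = 0.0942, 0.0994 and 0.0333), and with GC content matched the adjusted p was 0.0140, 0.00688 and 0.124. At a fold size of 1, nitrate and sulfate passed as well (adjusted p = 0.0234 and 0.0276). HMOX1, the inducible heme oxygenase, was at 2.74, 2.89 and 2.40 in the authors' deposited table.

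Past a fold size of 1.5 there were 650 genes with nitrate (300 higher, 350 lower), 791 with sulfate (365 higher, 426 lower) and 1338 with the mixture (666 higher, 672 lower). Of these, 476 passed in all 3 comparisons and 664 with the mixture but neither single salt. The salt doses differed, so the counts do not rank the salts. Both were ammonium salts, and no group had ammonium with another anion. Ammonium sulfate holds more ammonium per mole than ammonium nitrate, so the ammonium doses need not have differed. Effects of nitrate or sulfate and of ammonium therefore cannot be told apart. Across the 1541 genes, which are not independent replicates, Pearson's r was 0.978 between nitrate and sulfate, 0.916 between nitrate and mixture and 0.934 between sulfate and mixture. Unchanged groups that share controls gave a simulated r of 0.499 over all genes and 0.649 to 0.768 over the 20% to 1% of genes with the largest differences. The observed values lie above these, which already hold the effect of shared controls with the same spread as the treated groups. The controls could not be split, so how much of the observed r they account for is unknown. Higher genes were richer in GC than lower genes, with median transcript GC of 58.1% against 41.1% with the mixture and an area under the curve of 0.902 (95% bootstrap interval 0.885 to 0.919).

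Cytokine and cholesterol terms led the authors' deposited table of 57 GO terms. With nitrate, the 5 smallest p-values were for cellular response to tumor necrosis factor (35 of 224 genes, p = 2.4e-08), positive regulation of the ERK1 and ERK2 cascade (p = 3.4e-08), response to interleukin-1 (p = 2.3e-07), inflammatory response (p = 3.2e-06) and response to lipopolysaccharide (p = 5.0e-06) in the authors' deposited table. With sulfate, tumor necrosis factor (p = 4.1e-07), cholesterol biosynthesis (12 of 49 genes, p = 1.8e-06), interleukin-1 (p = 1.9e-06), cytokines (p = 8.9e-06) and negative regulation of proliferation (p = 9.5e-06) led the authors' deposited table. With the mixture, cholesterol biosynthesis came first in the authors' deposited table with 20 of 49 genes (p = 1.9e-09), followed by interleukin-1 (p = 1.0e-05), cell-cell signaling (p = 6.6e-05), cytokines (p = 7.7e-05) and cAMP (p = 0.000151).

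The moderate experiment asked for the response to the mixture over nanomolar to micromolar doses. Its comparisons are named Mix1 to Mix5 and are not tied to the 5 doses, so no dose was assigned and no dose trend was tested. In Mix1 and Mix2, the largest absolute values in the authors' deposited table were 5.04e-05 and 8.83e-06, and in Mix3 the values lay between -0.58 and 0.10. The sign was that of Mix5 for 97.9%, 99.1% and 100% of the 423 genes in Mix1, Mix2 and Mix3. Simulated unchanged groups with shared controls gave less, 83.9% to 94.98% over the 20% to 1% of genes with the largest differences. That simulation gave every group the same spread, unlike these values, so the excess does not tell whether these comparisons differed from control. The values of Mix1 and Mix2 were next to 0, with median absolute values of 1.6e-06 and 2.8e-06. No error came with them, and whether they had been shrunk toward 0 is unknown. Their size therefore does not show that expression in Mix1 and Mix2 was unchanged. AGR2, a disulfide isomerase of secretory epithelium (ENSG00000106541, chromosome 7, 16791811 to 16833433), was at -1.40 in Mix4 and -1.89 in Mix5, and SGK1, a kinase that regulates ion channels, at -1.41 and -1.75 in the authors' deposited table. CALM2, a calmodulin gene, was at -1.54 and -1.45, and FH, the fumarase of the citric acid cycle, at -1.04 and -1.49 in the authors' deposited table. The mitotic genes CCNB1, CCNB2 and AURKA were at -1.42, -1.30 and -1.20 in Mix5, and NDUFS1, UQCRC2 and ATP5F1A of the respiratory chain at -1.35, -1.06 and -1.05, in the authors' deposited table. Lower values were also listed for HSPA8, a chaperone, at -1.09 and LDHA, the lactate dehydrogenase subunit, at -1.09 in Mix5 in the authors' deposited table.

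Higher values in Mix5 included SLAMF9, a surface receptor (2.14), HES7, a transcriptional repressor (1.65), NPAS1 (1.58), LY6K (1.46) and PADI3, a protein deiminase (1.45), in the authors' deposited table. The metallothionein MT2A was at 1.02 in Mix4 and 0.95 in Mix5, KRT19 at 0.59 and 1.16, and CYP1A1, a target of the aryl hydrocarbon receptor, at 0.48 and 1.18 in the authors' deposited table. SULT1A4 had the lowest Mix5 value in the authors' deposited table, -2.86, and is uncertain because SULT1A3 is a near-identical copy. Past a fold size of 1 there were 146 genes in Mix4 (6 higher, 140 lower) and 364 in Mix5 (139 higher, 225 lower), with 87 in both. In Mix4, 1 of 8 lists had an unadjusted p under 0.05 by the exact binomial test, the metallothioneins with MT2A as their 1 member past that size (p = 0.0411, adjusted p = 0.329). Lists of lower genes could not pass there, because 140 of 146 genes were lower. No list had more than 3 members past that size in Mix5, too few to pass the test after adjustment. Every one of the 423 genes had the same sign in Mix4 and Mix5, against the same simulated 83.9% to 94.98%. The simulated groups had equal spread, unlike Mix1 to Mix5, so this excess does not show agreement beyond shared controls. GC content told higher from lower genes in Mix5 almost completely, with medians of 65.2% and 44.4% and an area under the curve of 0.995 (95% bootstrap interval 0.986 to 1.00).

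**Figure D2:**
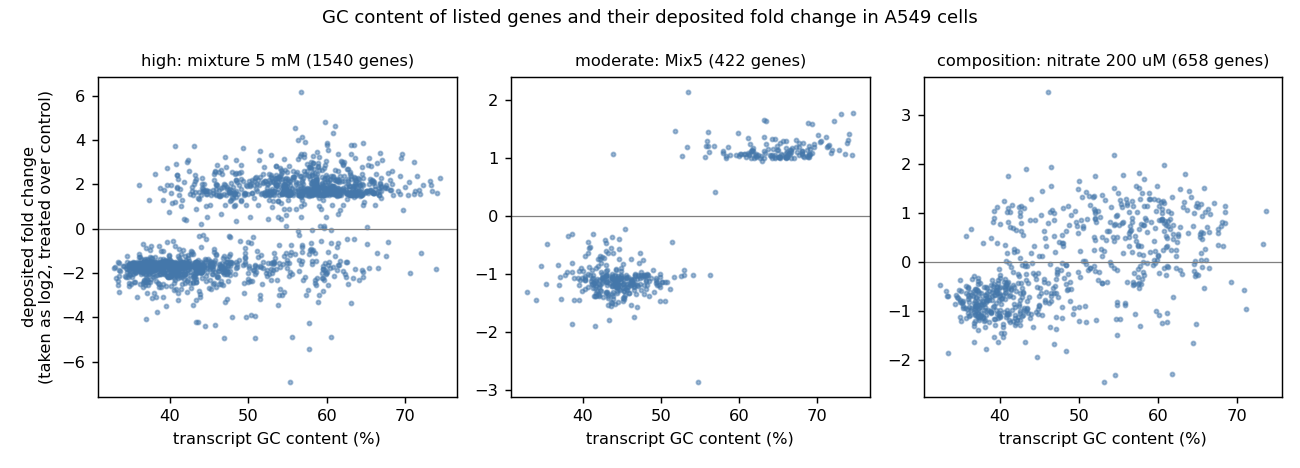
Transcript GC content in percent (horizontal axis) against the deposited fold change (vertical axis, taken as log2, treated over control) of listed genes in 3 comparisons of A549 cells. Each point is 1 gene. Past the fold size, genes above 0 have a higher median GC content than genes below 0 in all 3 panels, 65.2% against 44.4% in Mix5, while single genes overlap.

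In the authors' deposited table of GO terms for Mix5, anaphase-promoting complex-dependent catabolism led with 12 of 82 genes (p = 4.7e-06), followed by antigen presentation via MHC class I (p = 6.0e-05), mitochondrial ATP synthesis (5 of 19 genes, p = 0.000181), NIK/NF-kappaB signaling (p = 0.000222) and ubiquitin-independent proteasomal catabolism (p = 0.000235). For Mix4, toxin transport (p = 8.8e-05), pre-replicative complex assembly (p = 0.000147), protein deneddylation (p = 0.000231), positive regulation of establishment of protein localization to telomere (p = 0.000231) and of protein localization to the Cajal body (p = 0.000314) had the smallest p-values in the authors' deposited table.

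The composition experiment held the sum of nitrate and sulfate at 200 uM and varied the share of nitrate. Sulfate fell as nitrate rose, so effects of either ion, or of any ammonium given with them, cannot be told apart. U2AF1L5, a splicing factor gene (ENSG00000275895, chromosome 21, 6484623 to 6499261), was among the highest genes in all 5 comparisons, at 2.33, 2.41, 2.29, 3.74 and 3.49 with 0, 50, 100, 150 and 200 uM nitrate in the authors' deposited table. It is uncertain because U2AF1 is a near-identical copy. PLEKHG6 was at 2.27, 1.65, 1.17, 1.70 and 1.99 in the authors' deposited table. BST2, an interferon-induced gene that tethers virions, was at 2.45 without nitrate and between 0.59 and 1.41 in the other compositions in the authors' deposited table. IL1B was at 2.28 without nitrate and between 0.18 and 1.23 in the others, while CXCL8 was at -0.46 without nitrate and -1.86 with 200 uM nitrate, in the authors' deposited table. CXCL17, a mucosal chemokine, was at 1.44, 0.24, 2.00, 1.75 and 1.95, and SLC6A12, a betaine transporter, at 2.05, 1.09, 0.44, 0.07 and 1.19 in the authors' deposited table. MX1, an antiviral GTPase, was at 0.80, 1.39, 1.52, 0.67 and 1.03 in the authors' deposited table.

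Among lower genes, ITGB6, an epithelial integrin subunit, was at -2.35 with 100 uM of each salt, and SERPINB7, a serpin, at -2.03 without nitrate in the authors' deposited table. SULT1A3 lay between -2.36 and -1.34 over the 5 compositions and NBPF19 was at -2.13 with 50 uM nitrate in the authors' deposited table, both uncertain because of near-identical copies. Genes known mainly from immune cells were also listed, such as CLEC4E, a receptor of myeloid cells, at 2.20 without nitrate, and CD5, a lymphocyte receptor, at -1.78 with 50 uM nitrate in the authors' deposited table. No mean level came with these values, so whether they rest on more than a few reads is unknown. Past a fold size of 1 there were 265, 133, 194, 187 and 205 genes with 0, 50, 100, 150 and 200 uM nitrate, of which 156, 70, 38, 52 and 97 were higher. Only 10 genes passed in all 5 comparisons. No list had more than 3 members past that size in any comparison, too few to pass the list test after adjustment, so it says nothing there. Pearson's r across the 660 genes was 0.572 to 0.755, against a simulated 0.669 to 0.781 for unchanged groups with shared controls over the 20% to 1% of genes with the largest differences. Higher genes were again richer in GC than lower genes, with areas under the curve of 0.760 to 0.946.

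**Figure D3:**
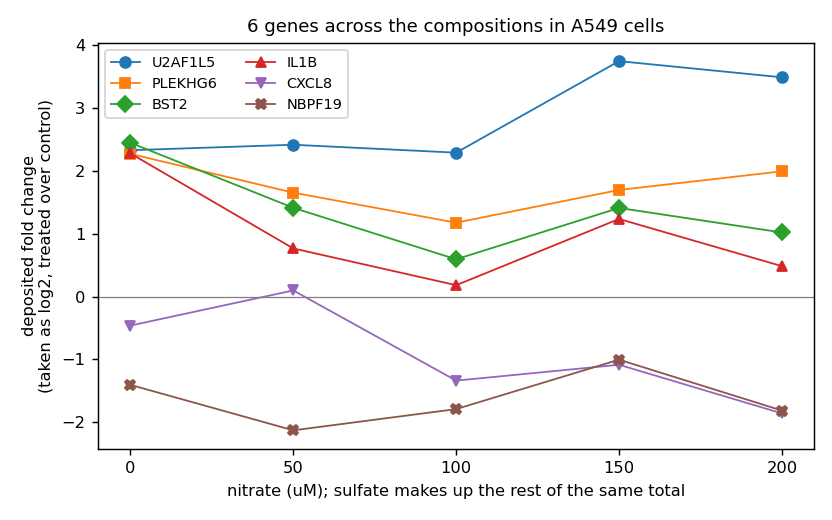
Deposited fold changes (vertical axis, taken as log2, treated over control) of 6 genes in A549 cells against the nitrate dose in uM (horizontal axis), with sulfate making up the rest of a 200 uM total. Each marker is 1 deposited value without error. IL1B and BST2 are highest without nitrate, at 2.28 and 2.45.

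The authors' deposited table of GO terms for the compositions lists 24 terms, most of them immune terms. That immune terms come first in it therefore says little about the cells. Without nitrate, positive regulation of natural killer cell cytotoxicity (4 of 13 genes, p = 3.0e-05) and of interferon-gamma production (6 of 43 genes, p = 3.7e-05) led the authors' deposited table. Positive regulation of granulocyte macrophage colony-stimulating factor production (p = 6.1e-05), chemokine signaling (p = 0.000131) and adaptive immune response (15 of 267 genes, p = 0.000259) followed in the authors' deposited table. With 50 uM nitrate, negative regulation of mast cell activation led the authors' deposited table (p = 5.9e-05), then synaptic vesicle budding (p = 0.000162), detection of other organism (p = 0.000210), adaptive immune response (p = 0.000241) and positive regulation of interleukin-6 production (p = 0.000330). The other compositions had larger smallest p-values in the authors' deposited table, 0.000182 for negative regulation of signaling with 100 uM nitrate, 0.00965 for positive regulation of regulatory T cell differentiation with 150 uM and 0.000687 for negative regulation of interleukin-12 production with 200 uM. Next with 100 uM came regulation of hemopoiesis (p = 0.000220), interleukin-27 signaling (p = 0.000827), synaptic vesicle budding (p = 0.00580) and chemokine signaling (p = 0.0138) in the authors' deposited table. With 150 uM these were MyD88-dependent toll-like receptor signaling (p = 0.0105), positive regulation of monocyte chemotaxis (p = 0.0139), negative regulation of interleukin-12 production (p = 0.0139) and T cell costimulation (p = 0.0261) in the authors' deposited table. With 200 uM, adaptive immune response (p = 0.00205), T cell costimulation (p = 0.00369), synaptic vesicle budding (p = 0.00606) and positive regulation of monocyte chemotaxis (p = 0.0137) followed in the authors' deposited table.

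In mouse lung, 87 genes past a fold size of 1 could be named, among them 3 heat shock genes. Hspa1a was at 3.00, Hspa1b at 2.52 and Hspb1 at 1.00 in the authors' deposited table, and the first 2 are near-identical copies. S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, were at -1.76 and -1.78, and the neutrophil collagenase Mmp8 at -1.45 in the authors' deposited table. Calca, which encodes calcitonin gene-related peptide, had the lowest named value in the authors' deposited table, -4.46, and the neuropeptide genes Vip and Grp were at -1.90 and -1.28. Rnase2a, an eosinophil-type ribonuclease, was highest at 4.27, Alox15 was at 1.02 and Chil1, a chitinase-like protein, at 1.35 in the authors' deposited table. Cd79a, Cxcr5 and Foxp3, known from lymphocytes, were at 1.19, 1.15 and 1.14 in the authors' deposited table. Mcidas and Ccno, which act in the formation of multiciliated cells, were at 1.38 and 1.24, the clock gene Nr1d1 at 1.26, and the mitochondrial genes mt-Atp8 and mt-Atp6 at -1.41 and -1.04 in the authors' deposited table. Lower ion channel genes included Kcnj16 at -3.17, whereas Kcnj14, of the same potassium channel family, was at 3.20 in the authors' deposited table.

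**Figure D4:**
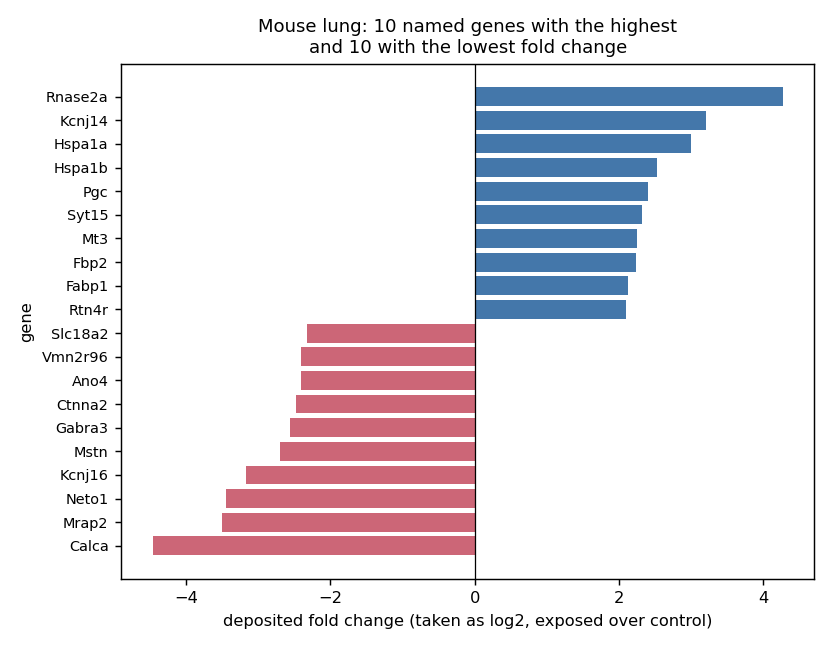
Deposited fold changes in mouse lung (horizontal axis, taken as log2, exposed over control) of the 10 named genes with the highest and the 10 with the lowest values. Bars start at 0 and carry no error. Rnase2a is at 4.27 and Calca at -4.46.

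Of 15769 mouse genes, 545 passed a fold size of 1 (202 higher, 343 lower), and 87.3% lay within 0.5 of 0. The remaining 458 genes past that size had no symbol, among them ENSMUSG00000089901 at 3.42 and ENSMUSG00000048758 at -5.66 in the authors' deposited table. Because the names come from GO terms made from genes past that size, the named genes are no sample of the whole table, and cell type lists could be counted only among them. All 3 named markers of monocytes and neutrophils were lower, against 1 each for alveolar type 2, club, T and B cell markers, all higher, and 1 for adipocytes, Cidea, which was lower. Chloride transmembrane transport had the smallest p in the authors' deposited table of mouse GO terms (5 of 44 genes, p = 8.2e-05), followed by astrocyte development (p = 0.000630), response to calcium ion (p = 0.00101), metabolism of 3'-phosphoadenosine 5'-phosphosulfate (2 of 5 genes, p = 0.00102) and leukocyte migration (p = 0.00121).

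Genes listed by more than 1 experiment were compared by sign. The high and composition tables shared 98 genes, and with nitrate at 10 mM and 200 uM the signs were the same for 80 of them, 81.6% (95% exact interval 72.5% to 88.7%). Pairing the signs at random within 3 ranges of GC content gives 77.3% for that pair (exact p = 0.139). Over the 15 pairs of these experiments the share was 74.5% to 82.7%, against 71.6% to 78.7% from such pairing, and no pair passed, adjusted or unadjusted (lowest exact p = 0.0665). The high mixture and Mix5 had the same sign for 39 of 51 shared genes, 76.5%, against 73.9% from such pairing (exact p = 0.331). Among genes at 1 or more in both tables, 3 of 20 pairs passed, 200 uM nitrate with each high treatment. The high treatments share their controls and at least 99.0% of their signs, so these 3 pairs are not separate results. With 10 mM nitrate, 24 of 25 signs were the same, 96.0%, against 71.6% from such pairing (exact test, adjusted p = 0.0132), though the highest of those ranges ran from 42.9% to 60.8% GC. The moderate and composition tables shared 1 gene. By symbol, 9 genes named in mouse were in the high table, and 4 of them had the same sign with the 5 mM mixture (exact binomial p = 1.00).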

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

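The fold sizes of the counts and list tests in the report, the tests at higher fold sizes and the matching and pairing on GC content were chosen only after the data were seen. The alternatives at a fold size of 1 in the high table, at 1.5-fold, at GO p under 0.01 and at 1 or more in both tables were planned before that. No paired analysis was possible because the tables hold comparisons and no values per sample. For the same reason no value could be had for another count test, other size factors, filters on low counts or mean levels, other pseudocounts, adjusted p thresholds of 0.01 and 0.1, leaving out a replicate, fits of only the groups compared, or an estimated correlation. Depth is unknown, so what it limits cannot be given. Changing the fold size moved the counts by construction, and in the truncated tables a lower size counts only genes already listed. At a fold size of 1, the high table had 1211 genes with nitrate and 1351 with sulfate, and at 2 it had 248, 294 and 483 with nitrate, sulfate and mixture. At 1.5-fold, there were 344 genes in Mix4, 473, 316, 400, 411 and 432 with 0, 50, 100, 150 and 200 uM nitrate, and 1536 in mouse lung. At 1.5 on the log2 scale there were 4 in Mix4, 18 in Mix5, 101, 24, 38, 29 and 33 in the compositions in that order, and 187 in mouse lung. GO terms at p under 0.01 numbered 4, 1 and 4 with 100, 150 and 200 uM nitrate, 26 with the high mixture and 26 in mouse lung.

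At a fold size of 1, the NRF2 list passed with nitrate (adjusted p = 0.0234) and sulfate (adjusted p = 0.0276), the lysosome list with nitrate (adjusted p = 0.0406), and the interferon list lost its call with the mixture (adjusted p = 0.311), by the entry of 2 lower genes. With GC content matched, the NRF2 list passed with nitrate (adjusted p = 0.0140) and sulfate (adjusted p = 0.00688) but not with the mixture (adjusted p = 0.124), and the glycolysis list did not pass with the mixture (adjusted p = 0.676). The immediate early, inflammatory and cholesterol lists kept their direction and their call with all 3 treatments, and the stress response list with the mixture, under both alternatives. The 3 treatments share their controls, so their list calls are not separate results. The same-sign shares of 81.6% (10 mM and 200 uM nitrate), 76.5% (high sulfate and no nitrate), 75.5% (high mixture and 100 uM of each) and 76.5% (high mixture and Mix5) passed against 50% but not against signs paired at random within GC ranges (exact p = 0.139, 0.739, 0.743 and 0.331). At 1 or more in both tables, 3 of 20 pairs passed the pairing test after adjustment, 200 uM nitrate with each high treatment (adjusted p = 0.0132, 0.00926 and 0.00926 for nitrate, sulfate and mixture). These 3 pairs are not separate results, because the high treatments share their controls.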

Other observations

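The test of shared controls, the random pairing of signs, and the fold sizes and GC matching used above, were chosen only after the result was seen. The other tests were written before their results were computed. The genes named in this paragraph were picked after their values were seen. SULT1A4, one of a near-identical pair, was at 3.89 with 10 mM nitrate but 0.13 and 0.11 with sulfate and the mixture, and at -2.86 in Mix5, in the authors' deposited table. SLX1B, also one of a near-identical pair, was at 4.05 with 50 uM nitrate and 0.15 with 100 uM in the authors' deposited table. Some genes named in mouse lung were in the high table with the other sign, such as Nr1d1, at 1.26 in mouse and between -2.37 and -1.99 in A549 cells, and Agt, at -1.15 in mouse and between 0.86 and 3.07 in A549 cells, in the authors' deposited table. Of the 9 shared genes, 4 had the same sign with the 5 mM mixture. Among these, Hspa1a was at 3.00 in mouse and between 4.37 and 4.80 in A549 cells in the authors' deposited table.

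Direction followed GC content in the A549 tables, and a GC bias between libraries is a candidate explanation. In Mix5 the area under the curve was 0.995 for GC content and 0.266 for transcript length (95% bootstrap interval 0.209 to 0.322), and with the 5 mM mixture it was 0.902 for GC content, all past the bounds of 0.7 and 0.3 set for such a bias. A response of the cells to the salts that happens to act on GC-rich or GC-poor transcripts would give the same values, and it was not tested, because no values per library were at hand. Where direction was compared with genes alike in GC content, the immediate early list with the mixture still passed (adjusted p = 6.8e-07), as did the cholesterol list (adjusted p = 1.8e-06), so GC content alone may not account for those groups. Transcript length was not matched. Higher genes were also shorter in the compositions, with areas for length of 0.179 to 0.322, and less so in the high comparisons, at 0.382 to 0.437. In Mix4 the interval for length held 0.5 (0.219 to 0.586).

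The 5 compositions moved together, with the same sign in all 5 for 66.4% of 660 genes against a simulated 65.4% to 89.0% for unchanged groups, and the shared control libraries are a candidate explanation. Among the 98 genes also listed in the high experiment, which has other controls, 78.6% had the same direction of the mean fold change (exact 95% interval 69.1% to 86.2%). An interval above 50% was to count against the controls alone, but that bound was wrong, because GC content told higher from lower genes in all 8 comparisons (areas of 0.752 to 0.946) and a GC difference of the controls in both experiments would give it too. In the middle GC range, from 39.8% to 47.1%, 71.9% of 32 shared genes had the same direction (exact 95% interval 53.3% to 86.3%), and an interval above 50% was to count against GC content, but that bound was wrong too: 24 of the 32 were lower in the high and 25 in the composition experiment, and pairing these signs at random gives 64.1% (exact p = 0.327). Over the 15 pairs of comparisons the share in that range was 65.6% to 81.25%, highest for 200 uM nitrate with each high treatment. Those shares were tested only against 50%, so they do not decide it. Signs paired at random within 3 ranges of GC content give 76.9% for the 98 genes (exact p = 0.722), and although 200 uM nitrate passed with 10 mM nitrate among genes at 1 or more in both tables (adjusted p = 0.0132), the highest range there ran from 42.9% to 60.8% GC, so shared controls, a GC difference and a shared effect cannot be told apart here.

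A graded effect of composition was tested by order, which cannot tell a rise in nitrate from the fall in sulfate. Of 660 genes, 13 had fold changes in strict order of nitrate dose, 4 upward and 9 downward, against 11 expected if all orders were alike (exact binomial p = 0.540). KLRK1 ran from 1.79 without nitrate to -0.53 with 200 uM and DNAJC5B from 0.30 to 1.28 in the authors' deposited table, and both are among those 13 and were chosen after their values were seen. Strict order was thus not clearly more frequent than if all orders were alike. The comparisons differed in size, with a mean absolute value of 0.917 without nitrate against 0.646 to 0.778 in the others. All orders need therefore not be alike even without a graded effect, and 11 is only a rough expectation. How often a graded effect would give strict order in values of unknown error was not tested. A graded effect on many genes therefore stays open, as does an effect on a few genes or one that is not graded.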
